A study of Homo sapiens with 6 samples.

How the data were processed

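The arrays carried biotin-labelled cRNA made from total RNA of 6 SH-SY5Y cultures, 3 with EGR3 overexpression and 3 with negative control particles, per the labels' protocols. The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes, which give no version of it. RMA corrects the background, normalizes quantiles between arrays and summarises the probes of a probe set. In the deposited table the median over the 6 arrays is 0, within 1e-06, in all 49395 rows, so each probe set had also been centred on its own median, a step that no label records. A log2 value is therefore a difference from that median and keeps no brightness. The base of the logarithm is not written in the table and is taken from what RMA gives. The medians of the arrays lay between -0.01 and 0.02 and their SDs between 0.18 and 0.30. Signal over background cannot be recovered from such values, so a gene near background cannot be told from a bright gene that differs little.

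Probe sets were named through the platform annotation supplied with the table. Of the 49395 probe sets, 44988 had 1 gene symbol, 1832 had several and were left out, 102 were control probe sets, and 2473 others had no symbol. A gene's value was the mean of its probe sets with only that symbol, leaving out those marked as open to cross-hybridisation (suffix _x_at) where the gene had another. This left out 6323 probe sets and gave 18132 genes from 38665 probe sets, 10617 of them with more than 1. The rule fixed before the data were examined was the probe set with the highest mean over the 6 arrays. It assumes values that keep brightness, so it was replaced after the table was opened, and the fixed rule taken literally was run as an alternative. Filters on dim genes, and the condition that a named gene be brighter than the median gene, could not be applied for the same reason.

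Differences between EGR3 overexpression and negative control were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 6 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over the 18132 genes and a threshold of 0.05. Every difference is overexpression minus control, and its error is the standard error of that difference. The exact permutation test of a single gene with 3 arrays against 3 cannot give a two-sided p under 0.1, so no such test was used. On simulated values for the 18132 genes of this comparison, 46% of genes changed by 0.5 (log2) were called with the right sign, 74% of those changed by 1, 100% of those changed by 2 and 100% of those changed by 3, and 0.0391% of unchanged genes were called. The simulated genes were drawn independently, with no array standing apart. In the data the estimated correlation within a list reached 0.961 (G2 and M phase), so these shares do not carry over to the real arrays.

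The choice of comparison, its tests of genes, lists and chromosomes, the gene lists, named genes and all but 2 of the alternatives was made before the data were examined. Tests of explanations that were chosen after the result was seen are named in the closing section. There were 32 lists with 1108 entries, written from general knowledge, of which 1018 were matched to a measured gene, 4 through an older symbol. They cover the Reelin pathway, EGR family and targets, immediate early genes, axon guidance and neurite outgrowth, presynaptic, postsynaptic, receptor, ion channel, neurotrophin and neuropeptide genes, markers of adrenergic and mesenchymal neuroblastoma and of Schwann, epithelial, hematopoietic and endothelial cells, the S and the G2 and M phases, p53, interferon and NF-kB genes, stress, cholesterol, glycolysis, oxidative phosphorylation and ribosomal genes, matrix, Wnt, Notch, TGF-beta, MAPK, MYC and apoptosis genes. Each list was tested with limma's camera (preset correlation of 0.01, Benjamini-Hochberg over the 32 lists), and again with an estimated correlation and with fry. The named genes were EGR3, RELN, other EGR, NAB and Reelin receptor genes, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap (leaving out open reading frame, antisense, pseudogene and LOC symbols), and per list up to 4 members with the smallest p past the threshold, or 2 where none passed. Genes were placed on chromosomes through the RefSeq table of assembly GRCh38.p14, which placed 18105 of them, and camera was run on the 24 chromosomes and on 871 windows of 40 neighbouring genes that start every 20 genes. The annotation names no genome build, so no coordinates are given.

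Alternatives were the replicate number as a block, centring or quantile normalization of the deposited values, the mean of all probe sets or the probe set with the largest variance, every probe set tested singly, a trend of the variance on the mean centred value with a robust prior, array weights, the ordinary test without eBayes, a threshold of 0.01, and each array left out in turn. The largest variance is taken over all 6 arrays with the group difference in it, so that choice favours large differences. Added after the values were seen were the literal probe set rule and the omission of both arrays that correlated least with their own group, overexpression replicate 2 and negative control replicate 3.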

Results

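Gene expression was measured on 6 Affymetrix PrimeView arrays hybridised with RNA from SH-SY5Y cells, an established human neuroblastoma line of adrenergic, neuron-like character. In 3 samples the cells had been infected with lentiviral particles that overexpress EGR3, a zinc finger transcription factor of the early growth response family. In the other 3 samples they had been infected with negative control particles. Both groups were selected with puromycin at 1 µg/mL from 3 days after infection, for 2 weeks, and each array used 5 µg of total RNA. The labels do not say whether the replicates of a group came from separate infections or from cultures of 1 stable line, so differences between lines that arose during selection cannot be told apart from those of the transgene. The table held 49395 probe sets, which gave values for 18132 genes. Each value is a log2 difference from the probe set's own median over the 6 arrays, so the level of one gene cannot be set against that of another, and the number of arrays limits the precision.

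The first comparison asked whether the overexpressed gene itself was higher. EGR3 was measured by 4 probe sets, and 1 of them carried nearly all of the difference. Probe set 11736342_at was higher by 0.91 ± 0.20 (log2, SE, n = 3 per group), or 1.88-fold, with values of 0.88, 0.12 and 0.62 in EGR3 overexpression replicates 1, 2 and 3 and of -0.55, -0.44 and -0.12 in the negative controls. Its adjusted p over all probe sets was 0.0502 (limma, Benjamini-Hochberg), just short of the threshold of 0.05. The other EGR3 probe sets differed by 0.04 ± 0.07, -0.02 ± 0.08 and 0.11 ± 0.09. Averaged over the 4 probe sets, EGR3 differed by 0.26 ± 0.08 with an adjusted p of 0.107 (limma), although every overexpression array lay above every control array. The data do not say which part of the transcript a probe set reads, so a probe set outside the construct would not see the transgene. EGR3 passed the threshold when overexpression replicate 2 was left out, with a difference of 0.32 and an adjusted p of 0.0254 (limma).

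The second comparison asked whether RELN, the gene named in the study's title, was higher with EGR3. RELN encodes Reelin, a secreted glycoprotein that guides neuronal positioning. RELN rose by 2.68 ± 0.11 (log2, SE, n = 3 per group), or 6.39-fold, with an adjusted p of 0.000291 (limma, Benjamini-Hochberg). Its values were 1.41, 1.18 and 1.54 in the 3 overexpression arrays and -1.33, -1.40 and -1.17 in the controls. All 4 RELN probe sets rose, by 2.41 to 3.01. The rise passed the threshold with each of the 6 arrays left out in turn, at 2.59 to 2.77.

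**Figure D1:**
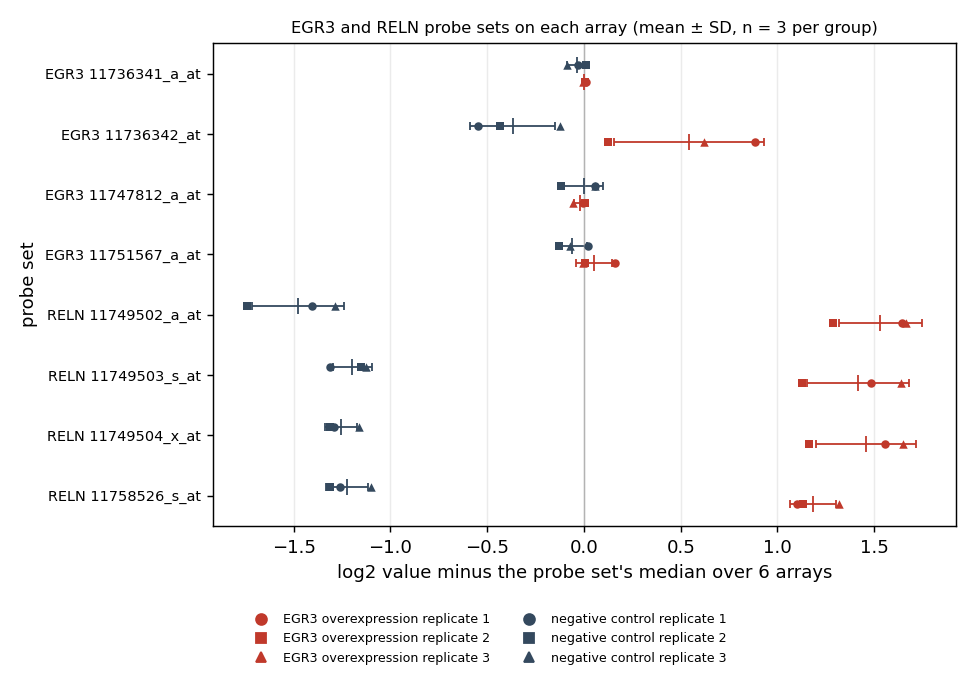
Values of the 4 EGR3 and 4 RELN probe sets on each of the 6 arrays, as log2 differences from the probe set's median over the arrays (horizontal axis); points are arrays, and bars are the group mean ± SD (n = 3). The groups stand apart by 2.41 to 3.01 at every RELN probe set, whereas among the EGR3 probe sets the largest difference is 0.91, at 11736342_at.

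Other genes of Reelin signalling were described as a list of 31 measured genes. Beside RELN, 3 of them fell. LRP8, which encodes the Reelin receptor ApoER2, fell by 0.94 on the log2 scale (adjusted p = 0.00438), DNMT1, a DNA methyltransferase, by 0.78 (adjusted p = 0.0151) and RAP1A, a small GTPase, by 0.49 (adjusted p = 0.0493, all limma). With each array left out in turn, LRP8 passed in all 6 fits, DNMT1 in 3 and RAP1A in 1, and RAP1A stood at -1.90 at its most variable probe set and at -0.03 at the one with the highest mean. The second receptor gene VLDLR differed by 0.17 and the adaptor gene DAB1 by 0.12, and neither passed the test. VLDLR stood at 0.31, -0.61 and 0.44 in overexpression replicates 1, 2 and 3, and it passed without replicate 2, at 0.50 (adjusted p = 0.0298). Adjusted over the list alone, 2 members were higher and 4 lower. Over all genes 5 were higher and 6 lower without overexpression replicate 2, 1 and 2 without replicate 1, and 1 and 1 without replicate 3 or negative control replicate 1 or 2. The list as a whole had a median difference of 0.01 and an adjusted p of 0.852 (limma's camera). The study's title names RELN and the Reelin pathway, so the list may have been chosen on these arrays and is not independent evidence.

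Across all genes, 430 rose and 783 fell with EGR3 overexpression (limma, Benjamini-Hochberg adjusted p under 0.05). The change was at least 2-fold for 64 of those that rose and 168 of those that fell. By the mean of a gene's probe sets, the largest rises were in DSP, the desmosomal plaque protein desmoplakin, at 3.57, followed by LRRC2 at 2.83, IFI16, an interferon-inducible DNA sensor, at 2.80, and RELN. Next came MXRA8 at 2.37, LONRF2 at 2.19, the LIM homeobox gene LHX8 at 2.08, the phosphatase gene PTPRR at 1.95, the presynaptic adhesion gene NRXN3 at 1.93, the glutamate receptor scaffold gene GRIP1 at 1.92, CCDC3 at 1.89 and the complement factor gene CFI at 1.87. The largest falls were in the kinase gene SGK1 at -2.78, the neuropeptide gene NMU at -2.65, FAM111B at -2.36, TMEM229A at -2.25 and BASP1, a growth cone protein gene, at -2.19. The transcription factor gene POU4F2 followed at -2.16, then TOP2A at -2.03, PLCXD3 at -1.99, NSG2 at -1.98, ASPM and CTSV at -1.97 each, and SLC18A1, a vesicular monoamine transporter gene, at -1.96. Among these, RELN, DSP, LRRC2, IFI16, MXRA8, LONRF2, NRXN3, GRIP1, SGK1, FAM111B, TMEM229A, NSG2 and SLC18A1 passed the threshold with any 1 of the 6 arrays left out, whereas CCDC3, BASP1, TOP2A, ASPM and CTSV passed it in only 1 of these 6 fits and LHX8 and PTPRR in 2. The order depends on that mean: at the most variable probe set MXRA8 rose by 3.76, more than LRRC2, IFI16 or RELN (2.83, 3.13 and 3.01), and POU4F2 stood at -3.03, below SGK1 at -2.88. Choosing the most variable probe set favours large group differences. IFI16 had the smallest p of all, with a difference of 2.80 ± 0.08 and an adjusted p of 5.17e-05 (limma).

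**Figure D2:**
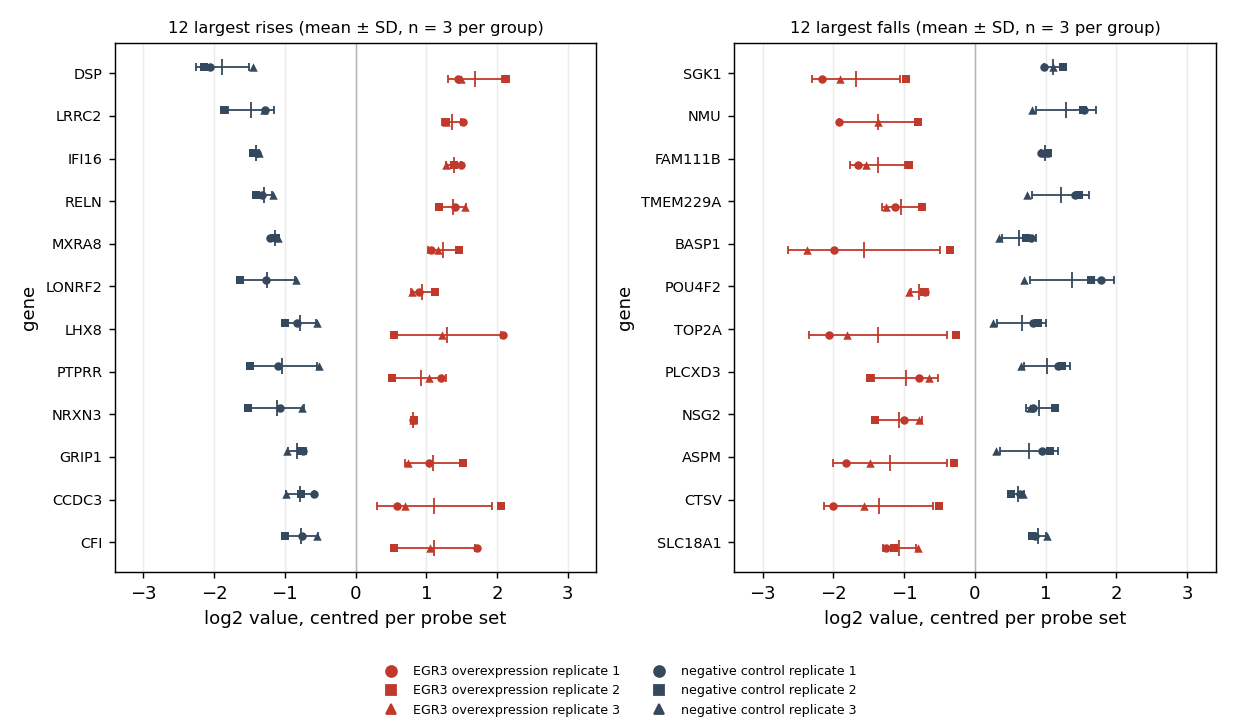
Values of the 12 genes with the largest rise and the 12 with the largest fall on each of the 6 arrays (horizontal axis, log2 difference from the median over the arrays); points are arrays, and bars are the group mean ± SD (n = 3). The groups do not overlap for any of these genes, because the rule that picked them required it. For TOP2A, ASPM, BASP1 and CTSV overexpression replicate 2 lies nearest to the controls, at -0.26, -0.30, -0.35 and -0.51.

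The counts depended strongly on single arrays. Every overexpression array lay above every control array for 2423 genes and below for 2644, together 27.9% of genes where chance gives 10%. The overexpression arrays did not form 1 tight group: across genes, which are not independent replicates, replicates 1 and 3 correlated at 0.851, whereas replicate 2 correlated with them at 0.0668 and 0.00214. Nor did the controls, where replicates 1 and 2 correlated at 0.693 and replicate 3 with them at 0.297 and 0.209. All these are correlations of centred values, not of whole expression profiles. Without overexpression replicate 2, 1819 genes were higher and 2027 lower (47.3% of calls higher, against 35.4% with it), and these included all 1213 genes called with it. Leaving out negative control replicate 1 lowered the total to 118 genes, and leaving out negative control replicate 2 lowered it to 144. Of the 69 other genes past the threshold that the fixed rule names, beside the largest changes, 14 passed with any 1 array left out and 25 passed in at most 1 of these 6 fits. At the most variable probe set 16 named genes past the threshold differed by over 1.5 times as much as by the mean: beside MXRA8, RAP1A and GAP43 these were SYN2 (1.40), DCN (1.25), PDGFRB (0.72), CORO1A (-1.17), ANKRD37 (-0.78), PFKFB4 (-1.40), RPL32 (0.89), SHANK2 (-1.21), GRIA3 (-0.75), CACNA1D (1.16), LOX (-1.66), TCF7L1 (0.75) and TNFRSF1A (1.22). All 16 moved away from 0, as that choice favours probe sets with a large group difference. At the probe set with the highest mean, an alternative added after the values were seen, SYN2 (0.44), ANKRD37 (-0.15), GRIA3 (-0.27), LOX (-0.12) and TCF7L1 (0.20) lay nearer to 0 and no longer passed.

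Among 30 measured genes of the EGR family, their NAB corepressors and EGR targets taken from the literature, 2 rose and 2 fell, or 3 and 2 adjusted over the list alone. NAB2, a corepressor that EGR proteins induce, rose by 1.18 ± 0.09 (adjusted p = 0.00247, limma) and was at 0.55, 0.51 and 0.51 in the 3 overexpression arrays. SYN2, a synaptic vesicle protein gene, rose by 0.89, whereas the cyclin gene CCND1 fell by 0.89 and the phosphatase gene DUSP4 by 0.78. EGR1 differed by 1.04, which did not pass the test (adjusted p = 0.139, limma), with values of 1.24, -0.11 and 1.19 in overexpression replicates 1, 2 and 3, and it passed without replicate 2, at 1.48 (adjusted p = 0.00081). EGR4 and NAB1 differed by -0.04 and -0.01, and no probe set was assigned to EGR2. The list's median was -0.02 (adjusted p = 0.809, camera). Of 35 immediate early genes JUN rose by 0.76 and DUSP4 fell, 1 in each direction also adjusted over the list alone, and the list's adjusted p was 0.559 (camera). Without overexpression replicate 2 the EGR list had 6 members higher and 3 lower and the immediate early genes 8 and 2, and with any other array left out at most 2 members of either list passed in either direction.

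Genes of axon guidance and neurite outgrowth, the process named in the study's title, changed in both directions. Of 69 measured members 5 rose and 14 fell, or 12 and 17 adjusted over the list alone. Over all genes 1213 of 18132 passed. The list as a whole did not pass (median 0.02, adjusted p = 0.809, limma's camera), but camera tests a shift in 1 direction, so members that move both ways can cancel. For changes in either direction fry gave an unadjusted p of 4.24e-06. That test does not set a list against other genes, and it gave 5.3e-05 for the postsynaptic list with 1 call. The plexin genes PLXNA4 and PLXNC1 rose by 1.03 and 0.62 and the semaphorin gene SEMA3C by 1.04. NEFM, a neurofilament gene, fell by 1.85 on the log2 scale (adjusted p = 0.00241, limma), and the growth cone gene GAP43 by 0.49 (adjusted p = 0.0479, limma), a call that held in only 1 of the 6 fits with an array left out and was lost at its most variable probe set (-1.13, adjusted p = 0.0758). As the title names neurite outgrowth, this list too may follow a choice made on these arrays and is not independent evidence. The counts were 3 and 2, 11 and 19, and 4 and 5 without overexpression replicates 1, 2 and 3, and 1 and 1, 1 and 1, and 5 and 8 without negative control replicates 1, 2 and 3.

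The presynaptic and the neuropeptide lists passed as lower, with the preset correlation only. Of 36 presynaptic genes 6 fell and 4 rose, or 14 and 4 adjusted over the list alone: the vesicle genes RAB3C, SYT4 and SYNGR3 fell by 1.33, 0.74 and 0.61, and NRXN3 and SYN2 rose. The presynaptic list had a median of -0.26 and an adjusted p of 0.01 (limma's camera with a preset correlation), which became an adjusted p = 0.799 with an estimated correlation. Of 31 neuropeptide and secretory granule genes, NMU, the galanin gene GAL (-1.48) and the granule protein gene VGF (-0.66) fell, 3 in all, or 4 adjusted over the list alone. That list had a median of -0.13 and an adjusted p of 0.0354 (camera), or adjusted p = 0.602 with an estimated correlation. The estimate was 0.00597, below the preset 0.01, yet the unadjusted p rose from 0.00793 to 0.0494 (camera). The neuropeptide list did not pass without overexpression replicate 2 (adjusted p = 0.104, camera), without negative control replicate 3 (0.0823), with array weights (0.0794) or without both of these arrays (0.186). The presynaptic counts of higher and lower genes were 2 and 3, 4 and 13, and 1 and 6 without overexpression replicates 1, 2 and 3, and 1 and 1, 1 and 2, and 2 and 6 without negative control replicates 1, 2 and 3. Those of the neuropeptide list were 2 and 6 without overexpression replicate 2, 0 and 0 without negative control replicate 1 and 0 and 2 without any other array.

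No other neuronal list passed camera. Among 16 neurotrophins and their receptors, SORCS1 rose by 1.06, LIFR by 0.78 and the GDNF family receptor gene GFRA2 by 1.24 while VGF fell, or 5 higher and 2 lower adjusted over the list alone (adjusted p = 0.165, camera, but 0.0194 as higher with the directional test fry). Of 35 voltage-gated channel genes, SCN3B fell by 1.05, CACNA2D2 by 0.84 and KCNC1 by 0.43, and CACNA1D rose by 0.50, the same 1 and 3 adjusted over the list alone (adjusted p = 0.693, camera). Of 35 glutamate and GABA receptor genes GRM7 rose by 0.86 and GRIA3 fell by 0.48, again 1 and 1 adjusted over the list alone (adjusted p = 0.984, camera). Of 26 postsynaptic scaffold and adhesion genes SHANK2 fell by 0.49, 1 gene by either adjustment (adjusted p = 0.984, camera). Without overexpression replicate 2 these lists had, in the same order, 5 members higher and 2 lower, 3 and 4, 3 and 2, and 4 and 2. With any other array left out the neurotrophin list had 2 or 3 higher and 0 lower, and the others at most 1 in either direction.

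Genes of the cell cycle were lower with EGR3 overexpression. Of 29 measured S phase genes 24 fell and 0 rose, 28 adjusted over the list alone, with a median of -0.97. They included the transcription factor gene E2F1 (-1.09), the helicase genes BRIP1 (-1.11) and MCM6 (-1.22) and the checkpoint gene CLSPN (-1.03), and the list's adjusted p was 1.69e-24 (limma's camera with a preset correlation) but adjusted p = 0.602 with an estimated correlation. All 33 G2 and M phase genes lay below 0, with a median of -1.62, yet only 5 passed the test, among them CENPF (-1.84), KIF11 (-1.60), CENPE (-1.77) and TOP2A (-2.03), and 33 adjusted over the list alone. This list had an adjusted p of 4.63e-17 (camera) and an adjusted p = 0.798 with an estimated correlation. The arrays differed in size: the G2 and M phase median was -1.83 and -1.58 in overexpression replicates 1 and 3 and -0.13 in replicate 2, and 0.53, 0.65 and 0.13 in the controls, while the S phase median was -0.80, -0.28 and -0.61 in the overexpression replicates. The S phase count was 12, 27 and 8 without overexpression replicates 1, 2 and 3 and 4, 4 and 13 without negative control replicates 1, 2 and 3. All 33 G2 and M phase genes passed without overexpression replicate 2, 2 passed without negative control replicate 3, and 0 passed with any other array left out.

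Genes of glycolysis and the response to low oxygen were lower as well. Of 32 measured members 16 fell and 0 rose, 24 adjusted over the list alone, with a median of -0.59. They included ENO2 (-1.14) and ALDOC (-0.87), which encode the neuronal enolase and aldolase, PFKFB4 (-0.72) and ANKRD37 (-0.47), and the list's adjusted p was 5.71e-15 (limma's camera) and adjusted p = 0.602 with an estimated correlation. The count was 1, 27 and 3 without overexpression replicates 1, 2 and 3 and 1, 1 and 11 without the negative control replicates in the same order, and without overexpression replicate 2 a further 2 members rose. Of 39 oxidative phosphorylation genes COX8A (-0.41) and UQCRC1 (-0.43) fell and 0 rose, or 2 lower and 1 higher adjusted over the list alone. That list's median was -0.09 with an adjusted p of 0.0211 (camera), or adjusted p = 0.673 with an estimated correlation, and the call was also lost without overexpression replicate 3 (0.128), at the most variable probe set (0.0656) and at the one with the highest mean (0.0802). Of 41 cytosolic ribosomal protein genes RPL32 rose by 0.45, 0 adjusted over the list alone, with a median of 0.08 and an adjusted p of 0.0354 (camera), or adjusted p = 0.971 with an estimated correlation; the call was also lost without overexpression replicate 1 (0.208), replicate 3 (0.0914) or negative control replicate 3 (0.139), and with quantile normalization (0.0522). Without overexpression replicate 2, 4 oxidative phosphorylation genes were higher and 11 lower, and 9 ribosomal protein genes higher and 0 lower, and 0 of both lists passed with any other array left out.

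Genes of the unfolded protein and amino acid stress response were higher as a list, although 0 of the 34 measured members passed the test, by either adjustment. The list's median was 0.77 and its adjusted p 0.01 (limma's camera), or adjusted p = 0.971 with an estimated correlation. Its median was 1.12 in overexpression replicate 1, 1.28 in replicate 3 and -0.09 in replicate 2, against -0.07, -0.09 and 0.04 in the controls. DNAJB9, a chaperone gene, differed by 0.37 (adjusted p = 0.0531) and ATF4, the transcription factor of the amino acid response, by 1.22 (adjusted p = 0.07, both limma). Chosen after their values were seen, the amino acid response genes CHAC1 and ASNS stood at 3.16, -0.08 and 2.76 and at 2.52, -0.17 and 2.51 in overexpression replicates 1, 2 and 3, whereas the endoplasmic reticulum chaperone gene HSPA5 stood at -0.51, 0.11 and -0.55 and MANF at -0.76, -0.03 and -0.88. Without replicate 2, 24 members rose and 5 fell, ATF4 (adjusted p = 5.37e-05) and DNAJB9 (0.0154) among those that rose, and 0 passed without any other array.

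**Figure D3:**
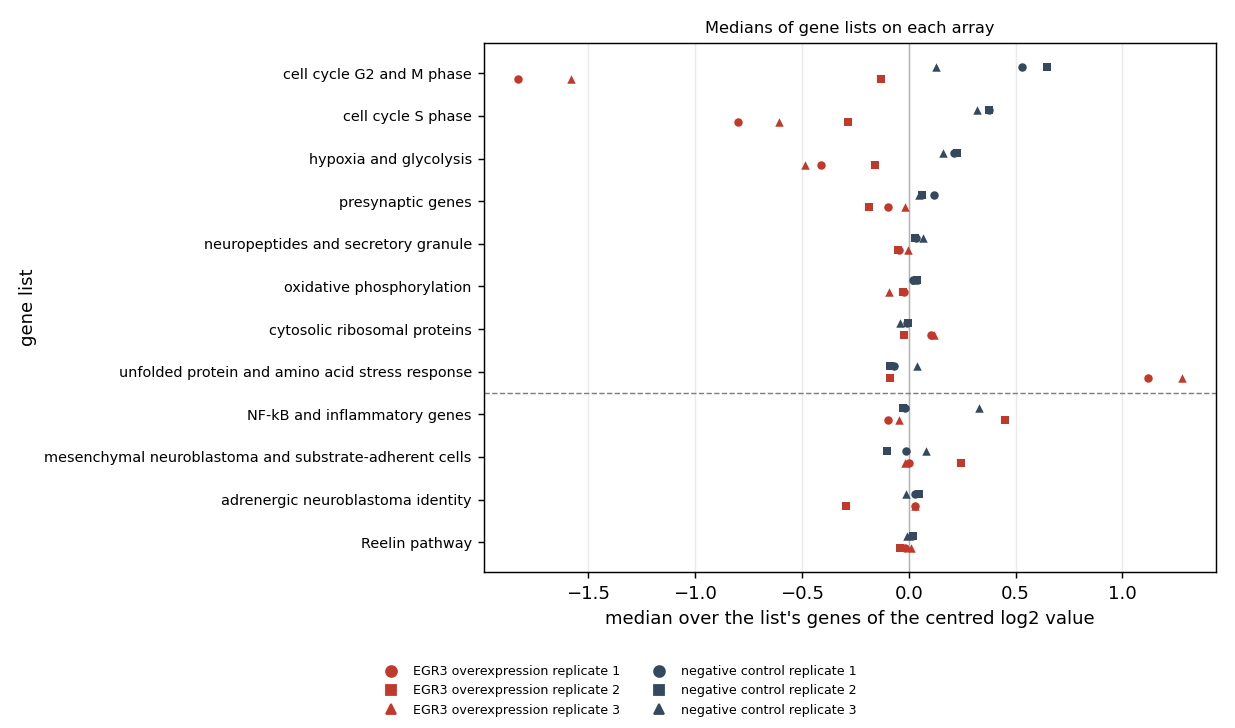
Median over the genes of a list on each of the 6 arrays (horizontal axis, log2 difference from each probe set's median over the arrays), with 1 point per array. Above the dashed line are the 8 lists past the camera threshold and below it 4 others. Overexpression replicate 2 lies apart from replicates 1 and 3 in the amino acid stress list (-0.09 against 1.12 and 1.28) and in the G2 and M phase list (-0.13 against -1.83 and -1.58).

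No list of cell type markers passed the test as a whole. Of 34 genes of adrenergic neuroblastoma identity 5 fell and 1 rose, or 8 and 3 adjusted over the list alone: SLC18A1, CYB561 (-0.89) and the transcription factor gene HAND1 (-1.09) were among those that fell, and ISL1 rose by 0.60 (adjusted p = 0.172 for the list, limma's camera). Of 41 genes of mesenchymal neuroblastoma and substrate-adherent cells DCN, PDGFRB and TBX18 rose, by 0.81, 0.41 and 0.38, and 0 fell, or 5 and 0 adjusted over the list alone (adjusted p = 0.165, camera). Both lists moved in overexpression replicate 2, with medians of -0.29 and 0.25 there, against 0.03 and 0.00 in replicate 1 and 0.03 and -0.02 in replicate 3. The mesenchymal list passed without replicate 1 (adjusted p = 0.0339) and without replicate 3 (0.00545), and the adrenergic list without the same arrays (0.031 and 0.0298, camera with the preset correlation). With an estimated correlation, run on all 6 arrays only, each had an adjusted p = 0.971. Without replicate 2 the mesenchymal list turned to lower (median -0.04, adjusted p = 0.764), with 7 members higher and 6 lower, and the adrenergic list had an adjusted p of 0.981, with 5 and 7; with any other array left out they had at most 2 and 0, and at most 1 and 3. Of 17 Schwann and glial genes NES and GAP43 fell, 2 by either adjustment (list adjusted p = 0.703), of 18 hematopoietic and endothelial genes CORO1A fell, 1 by either adjustment (0.54), and of 18 epithelial genes 0 passed by either adjustment (0.998, all camera), with EPCAM at 1.04, which passed without overexpression replicate 2 (adjusted p = 0.000259), and CLDN7 at -0.32. Without overexpression replicate 2 the last 3 lists had 1 member higher and 3 lower, 0 and 2, and 1 and 1, and with any other array left out 0 higher and at most 1 lower each.

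Lists of signalling and stress pathways gave few calls on all 6 arrays. Of 54 matrix and integrin genes LAMB1, MMP2 and LAMB2 rose by 0.44, 0.48 and 0.42 and LOX fell by 0.89, the same 3 and 1 adjusted over the list alone (list adjusted p = 0.272, camera, but 0.0359 and 0.0117 without overexpression replicate 1 or 3, and adjusted p = 0.971 on all arrays with an estimated correlation). Of 28 Notch genes HEY1, HES6 and HES4 fell among 4, by 0.59, 0.42 and 0.43, and DTX4 rose by 1.07, or 3 higher and 4 lower adjusted over the list alone (0.703). Of 35 Wnt genes TCF7L1 and LGR5 rose by 0.47 and 0.83, 2 by either adjustment (0.984). Of 34 TGF-beta and BMP genes BMP7 fell by 1.44 (adjusted p = 0.00478, limma), 1 by either adjustment (0.54), and of 19 MAPK feedback genes CCND1, ETV4 (-0.54) and DUSP4 fell and SPRED1 rose by 0.42, or 4 and 1 adjusted over the list alone (0.852). Of 25 p53 targets GADD45A rose by 0.41 while SESN1 and DDB2 fell by 0.40 and 0.72, or 3 higher and 2 lower adjusted over the list alone (0.427). Of 19 cholesterol synthesis genes STARD4 rose by 0.54 and EBP fell by 0.88, or 1 and 5 adjusted over the list alone (0.54), and of 33 apoptosis and survival genes TNFRSF1A rose by 0.79, 0 adjusted over the list alone (0.809, all camera). Without overexpression replicate 2 the matrix list turned to lower (median -0.02, adjusted p = 0.39), with 5 members higher and 11 lower, and the other lists had, in the same order, 3 and 5, 2 and 3, 3 and 6, 5 and 4, 4 and 5, 2 and 5, and 3 and 3. With any other array left out at most 2 members of each list passed in either direction. The TNFRSF1A call held in 2 of the 6 fits with an array left out, and the gene stood at -0.13 at the probe set with the highest mean.

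Interferon, inflammatory and ribosome assembly genes gave 0 calls on all 6 arrays, over all genes and adjusted over the list alone. Without overexpression replicate 2 they gave 1 higher and 3 lower, 0 and 1, and 1 and 3, with OAS1, LDHA and NOP56 among the lower ones, and without any other array 0. The smallest p-values belonged to OAS1 (-0.50) and HLA-B (0.20) among 40 interferon response genes, to CCL20 (0.14) and TNFAIP2 (-0.15) among 25 NF-kB and inflammatory genes, and to LDHA (-1.16) and NOP56 (-0.29) among 26 MYC and MYCN targets of ribosome assembly. Their lists had adjusted p-values of 0.982, 0.943 and 0.506 (limma's camera). The NF-kB list passed in the direction of lower without overexpression replicate 2 (adjusted p = 0.0332, camera), where its median had been 0.45, and had an adjusted p = 0.995 on all arrays with an estimated correlation.

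In all, 8 of the 32 lists passed with camera's preset correlation, 2 higher and 6 lower, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. That setting raised the p of the neuropeptide list although the estimate there lay below the preset value. The lost calls therefore do not measure correlation between genes alone. The directional test fry, which does not set a list against other genes, passed 3 lists: S phase (adjusted p = 0.0338), glycolysis and low oxygen (0.0351) and neurotrophins (0.0194, higher). Other splits of the 6 arrays into 3 and 3 gave up to 15 lists with the preset correlation, and 0 genes past the threshold. Each of them mixes the 2 groups, so the group difference adds to its residual spread. Their counts are therefore not a chance level.

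Neighbouring genes were compared because stable lines can differ in copy number. None of the 24 chromosomes passed as a whole (0 with an adjusted p under 0.05 and 0 with an unadjusted one, camera). Of 871 windows of 40 neighbouring genes 4 passed, 3 higher and 1 lower. The lower one, from CILP2 to PLEKHF1 on chromosome 19, holds mostly ZNF zinc finger genes, and 12 of its genes fell, among them ZNF826P (-1.51), ZNF257 (-1.08), ZNF726 (-0.86) and ZNF681 (-0.85), which were chosen after their values were seen (median -0.17, adjusted p = 0.00187, camera). In the window from RAB28 to SMIM20 on chromosome 4, 9 genes rose and 1 fell (median 0.17, adjusted p = 0.00747), and the remaining pair overlap on chromosome 22, from C22orf23 to CSDC2 (medians 0.12 and 0.14, adjusted p = 0.0194 and 0.00747). None passed with an estimated correlation (adjusted p = 0.994 for each of the 4) or without overexpression replicate 2.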

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

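The literal probe set rule and the omission of both least correlated arrays were chosen only after the values were seen. RELN kept its direction and its call in every alternative run. The number of genes called did not hold. Leaving out 1 array gave 55 to 1819 higher and 63 to 2027 lower genes, of which 26 to 136 and 38 to 338 changed at least 2-fold. In all, 302, 3846 and 347 genes passed without EGR3 overexpression replicates 1, 2 and 3, and 118, 144 and 702 without negative control replicates 1, 2 and 3, against 1213 with all arrays. The number of arrays alone does not set these counts, since leaving out overexpression replicate 2 and negative control replicate 3 together gave 4605. Those arrays had the lowest array weights, 0.239 and 0.627. The cause of the rise without overexpression replicate 2 was not tested.

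Array weights gave 2118 higher and 2339 lower genes (122 and 330 at least 2-fold), and omission of both least correlated arrays 2204 and 2401 (139 and 360). All 1213 genes kept their call in both. The ordinary test gave 25 and 21 (7 and 3), a threshold of 0.01 gave 79 and 123 (34 and 57), and a variance trend with a robust prior gave 716 and 1019, a trend on centred values that says nothing of intensity. At least 2-fold, the probe set with the largest variance gave 127 higher and 262 lower genes and testing every probe set 131 and 254. The share of calls that were higher was 35.4% and moved to 37.1% and 37.4% with centring and quantile normalization, to 47.5% with array weights, to 47.9% without both arrays and to 54.3% with the ordinary test.

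EGR3 differed by 0.20 to 0.32 with 1 array left out. It passed the threshold without overexpression replicate 2 (0.32), with array weights (0.32), without both arrays (0.35) and with its most variable probe set (0.91). Its adjusted p (limma) was 0.0441 in the last and lay between 0.0106 and 0.309 over all its alternatives. The most variable probe set was picked on a variance that includes the group difference, so that pass is not independent support. With the literal probe set rule 298 genes were higher and 537 lower. Of the 1213 genes called on the main values, 750 kept their call under it and 12 turned sign. TNFRSF1A, which rose by 0.79, stood at -0.13 with that rule, where another probe set stands for the gene. Among other comparisons of named genes with alternatives 440 lost the threshold, 31 gained it and 1240 kept their side. For lists, 25 lost it and 8 gained it. With an estimated correlation 0 lists and 0 windows passed, and fry passed 3 lists. Windows past the threshold numbered 0 without overexpression replicate 2 and 6 without replicate 1.

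With the replicate number as a block, 108 genes were higher and 192 lower (46 and 83 at least 2-fold). Same-numbered arrays did not deviate together (correlations across genes of 0.147, -0.267 and -0.258), and not every array correlated best with its own number. Whether the numbers pair the samples stays open, since the labels do not say. Overexpression replicate 2 and negative control replicate 3 dominate these deviations, so the correlations cannot exclude a shared culture or day. Not run, for lack of brightness in the values, were both filters on dim genes, the list members above the lower quartile and the chromosome test on brighter genes. The trend and ordinary test do not enter camera and were not run for lists.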

Other observations

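The tests chosen only after the result was seen are those of a mislabelled control, of the adrenergic and mesenchymal markers, of the order of EGR1, of the chromosome 19 window, and of the splits for the count of genes. Genes named here outside the fixed rule were chosen after their values were seen.

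Inflammatory genes were high on 1 array of each group. The NF-kB and inflammatory list had a median of 0.45 in EGR3 overexpression replicate 2 and 0.33 in negative control replicate 3, and lay between -0.10 and -0.02 on the other 4 arrays. The interferon list stood at 0.18 and 0.20 on the same arrays. IER3 was at 2.83 and 2.76, the neutrophil chemokine gene CXCL8 at 2.16 and 2.70 and the adhesion receptor gene CD44 at 1.50 and 1.35. In overexpression replicate 2 the osteopontin gene SPP1 stood at 3.41, NNMT at 3.31, CEBPD at 3.08 and VCAM1 at 2.96, with 1.18, 0.92, 1.25 and 0.65 in negative control replicate 3.

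Control probe sets also differed between arrays. The median of the hybridisation spikes was -0.24 in overexpression replicate 2 and between -0.00272 and 0.0346 elsewhere. The probe sets for the 5′ and 3′ ends of ACTB stood at -0.69 and -0.40 in overexpression replicate 1, 0.33 and 0.15 in replicate 2 and -0.64 and -0.41 in replicate 3, and at 0.369 and 0.265 in negative control replicate 3 and between -0.03 and 0.03 in the other controls. Those of GAPDH were close to each other in the overexpression arrays, at -0.39 and -0.31, -0.06 and -0.07, and -0.35 and -0.33.

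Overexpression replicate 2 stood apart from replicates 1 and 3, with 424 genes differing from their mean by over 1 (log2), 322 higher and 102 lower. Noise of single probe sets is argued against as the whole cause, since this deviation correlated at 0.735 between 2 probe sets of the same gene, over 10617 genes. Whether the 2 probe sets share probes could not be checked, so part of the correlation may be noise in common. A mislabelled control is argued against by genes called at 2-fold or more without replicate 2 and without 1 control, each in turn: replicate 2 showed over 50% of the change of replicates 1 and 3 in at least 37.7% of them and the held-out control in at most 3.81%. In most of these genes replicate 2 still lay nearer to the controls, with a median of 37.1% to 45.9% of the change, against -3.94% to 13.9% in the held-out controls. An earlier test decided less: of 474 genes called without replicate 2, it lay beyond all 3 controls in 81.4%, short of a bound of 90%, and negative control replicate 3, held out, lay beyond the other two in 72.5%. CHGA, CHGB and SCG2 lay at -3.21, -3.04 and -1.65 from the mean of replicates 1 and 3. The adrenergic list had a median of -0.25 (SD 0.90 over 34 genes). Whether fewer adrenergic cells were the whole cause of these falls is not decided by this. The genes belong to that list and were chosen after their falls were seen, so they would lie below its median whatever the cause. More mesenchymal cells stay open: the mesenchymal list had a median of 0.43, with 32 of 41 members higher, and the adrenergic list lay below all 10000 random lists of its size. Lists that mark no cell type were as extreme. The G2 and M phase list (median 1.54) lay above all random lists and the amino acid stress list (-1.16) below all. Random lists do not keep genes that move together, so such a position does not by itself point to a cell type. Such a mixture, with cells that escaped puromycin selection or with others, cannot be told apart from a changed state of the same cells, and either may account for part of the array. The design names no difference between replicates of a group to test.

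The EGR3 probe sets moved apart, with 0.91 at 1 of them and 0.11 or less at the others. A candidate explanation is that this probe set reads native EGR3 induced together with EGR1, as immediate early genes are. It had the order of EGR1 over the 3 arrays in 1 of 2 groups, the overexpression group, so this cannot be told from a probe set that reads the transgene. The position of the probe sets relative to the construct is not in the data. NAB2, at 0.51 in overexpression replicate 2 where EGR1 was at -0.11, was as high there as in replicates 1 and 3.

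ZNF genes in 1 window of chromosome 19 were lower, with 11 of 30 past the threshold and a median of -0.35. A loss of ZNF signal over the whole array is argued against, since 461 ZNF genes elsewhere had a median of 0.074 (95% bootstrap interval 0.05 to 0.10), with 10 lower and 10 higher past the threshold. The interval resamples genes with the arrays held fixed, so it carries no spread between arrays and speaks of these arrays only. A copy number loss stays open: the window's 10 other genes had a median of -0.03, which is 0.32 above that of its ZNF genes (permutation p = 0.0543, two-sided), with 1 past the threshold. This comparison cannot decide it, since the window was picked for its low values and holds mostly ZNF genes. Most of the other genes also lie before or after the ZNF genes. LINC00663 (0.13) and ACTR2P2 (0.12) lie among them, and 23 of the 30 ZNF genes were below 0. Regulation shared by the clustered ZNF genes, or probes shared among these similar genes, may also account for the pattern, and neither was tested.

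The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. Every split but the real one mixes the 2 groups, so the group difference adds to its residual spread. The other counts are therefore not a chance level. Those splits that gave 15 lists set overexpression replicates 1 and 3 against replicate 2. The real split gave 1213 genes and the highest other 0 (limma; with unadjusted p under 0.05, 4124 genes and at most 1583), so 1 of the 10 splits gave as many. It gave 8 gene lists and the highest other 15, and 6 of the 10 splits gave as many lists. It gave 4 windows and the highest other 3, and 1 of the 10 splits gave as many.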
